A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

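Small RNA libraries of 18 to 30 nt from 1 WT and 1 AGO1DCR1 culture were used, 1 library per group. The authors deposited, for each library, a list of distinct 36-nt reads with the count of each, which the values show to be whole numbers. The reads still carried the 3′ adapter and no alignment, and the steps by which the lists were made are not given in the sources used here.

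The adapter was found in each read as the leftmost position where the rest of the read matched it with at most 1 mismatch per 6 nt compared. Inserts of 18 to 30 nt were obtained from 50.9% of the WT reads and 66.4% of the AGO1DCR1 reads, and those with an undetermined base (36478 and 242345 reads) were left out. The remaining 10554288 and 13005889 inserts were the denominator of all values in RPM, as fixed before the data were examined. 3 reads, the floor used where a library had no read, equal 0.284 and 0.231 RPM.

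Inserts were matched to both strands of the R64 genome without mismatch, since the files hold no coordinates, and annotation was taken from the same assembly, whose genes are coding extents without UTRs. The reference used has no plasmid or virus sequence. Mitochondrial sequence formed 1 class of its own, so rRNA and tRNA genes mean the nuclear ones wherever their reads were left out or used for scaling, and leaving out mitochondrial rRNA and tRNA reads too was an alternative. A read with several matches was split equally over them and assigned by its middle base. Among reads of 22 and 23 nt, 75.7% in the WT library and 39.3% in the AGO1DCR1 library matched perfectly, and a further 10.4% and 19.4% matched with 1 mismatch. The most frequent 18-nt sequence without a genome match was read with 1 mismatch in 12.6% of WT cases and 39.8% of AGO1DCR1 cases, counting its copies with 0 or 1 mismatch. Reads lost in this way lower AGO1DCR1 values in RPM more than WT values.

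With 1 library per group no test was made and no p-value is given. Shares have exact Clopper-Pearson intervals, levels exact Poisson intervals and ratios conditional exact binomial intervals, at 95%, and all cover counting error only, since reads were not marked by molecule. Pairs of opposite-strand reads were counted once per pair of occupied positions over overhangs of -10 to 10 nt, from reads with 1 genome match. Genes needed 50 reads over both libraries, with rRNA and tRNA genes left out. Convergent, tandem and divergent regions were the gap or overlap of neighbouring protein-coding genes. Gene lists used log2 of RPM plus 1 over members with at least 10 reads and 10000 random lists drawn within 20 bins of level. Clusters joined reads within 100 nt.

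The named genes are the 12 largest and 6 smallest ratios, the 6 genes with the most antisense AGO1DCR1 reads, the 2 members of each list with the most AGO1DCR1 reads, and the 6 clusters with the most AGO1DCR1 reads. A value of exactly 0 was set at the floor, as the rule was written. Genes with mostly single-position reads were added after the values were seen. Alternatives covered the lengths, rRNA and tRNA reads, distinct sequences, reads with several matches, scaling, minimum reads, thresholds, pseudocounts of 0.1 and 5, and merging distances of 30 and 300 nt.

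The steps were tested on simulated data. Of 20000 simulated reads, 99.9% were trimmed at their true length. Of 200 genes simulated with a 16-fold change between AGO1DCR1 and WT, 200 were found at least 8-fold higher, as were 0 of 1476 unchanged genes with enough reads. These values hold for the simulated data only. In the AGO1DCR1 library the most frequent sequence without a genome match was read with a mismatch in 39.8% of the cases counted above. The median ratio of genes with enough reads was 52.7, above the simulated 16-fold change. The simulations therefore cannot show how often trimming or gene calls are wrong in these libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.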

Results

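Small RNAs of *Saccharomyces cerevisiae* were sequenced from a wild-type (WT) strain and from a strain named AGO1DCR1, to which RNA interference had been restored. *Saccharomyces cerevisiae* itself lacks this pathway. Its core proteins are Dicer, which cuts double-stranded RNA, and Argonaute, which binds the products. Both cultures were grown to log phase at 30 °C, and RNA of 18 to 30 nt was selected. There was 1 library per strain. The WT library held 20786905 deposited reads, of which 10554288 gave an insert of 18 to 30 nt without an undetermined base. The AGO1DCR1 library held 19953352 and 13005889. Perfect matches to the R64 genome were found for 52.7% of the WT inserts and 36.8% of the AGO1DCR1 inserts. With no replicates, no test between the strains was possible and no difference has a replicate check. Intervals are exact 95% intervals for counting error in these 2 libraries only.

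The first comparison asked whether reads of the size of Dicer products, 22 and 23 nt, were more frequent in the AGO1DCR1 library. Reads of 22 or 23 nt made up 19.5% of the WT library (Clopper-Pearson interval 19.51 to 19.56%) and 42.6% of the AGO1DCR1 library (42.56 to 42.61%), a ratio of 2.18. A single fragment of 18S ribosomal RNA, 23 nt long, gave 963228 WT reads, 46.7% of the WT reads of 22 and 23 nt, and 168 AGO1DCR1 reads. It matched both annotated copies of the 18S gene on chromosome XII of R64, at 457710 to 457732 in RDN18-1 and at 466847 to 466869 in RDN18-2. Without reads of nuclear rRNA and tRNA genes, which are meant below wherever rRNA and tRNA reads are left out or used for scaling, the ratio was 4.13. Among genome-matching reads outside nuclear rRNA and tRNA genes, the most frequent WT length, 30 nt, held 10.7% of reads. In the AGO1DCR1 library 25.7% were 23 nt and 21.6% were 22 nt, while 0.844% were 24 nt. Reads of 20 and 21 nt were also frequent in that library, at 18.7% and 18.1%.

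**Figure D1:**
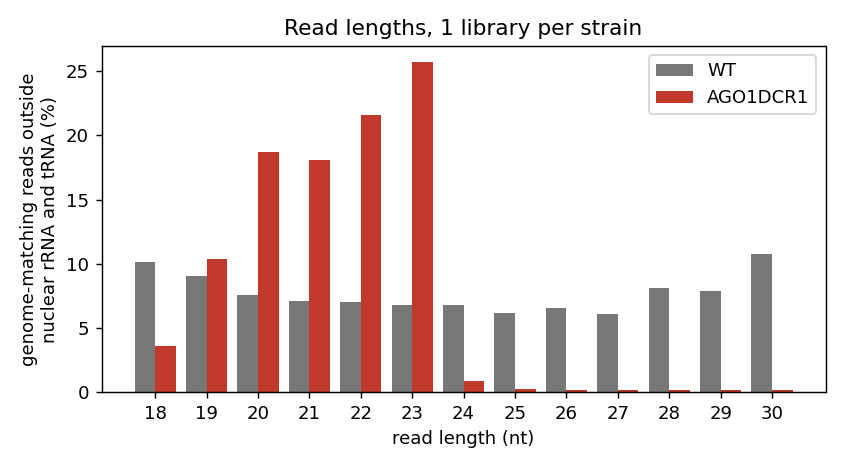
Length of genome-matching reads outside nuclear rRNA and tRNA genes, in nt on the x axis, as a percentage of such reads in each library on the y axis; grey bars are WT and red bars AGO1DCR1, 1 library each. The AGO1DCR1 library has 25.7% of its reads at 23 nt and 0.844% at 24 nt, and the most frequent WT length holds 10.7%.

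Argonaute of budding yeasts is known to bind mostly small RNAs that start with U. A U stood at the 5′ end of 68.9% of the WT reads of 22 and 23 nt (68.87 to 68.99%) and of 33.7% of those of the AGO1DCR1 library (33.62 to 33.70%). The 18S fragment starts with U. At the other lengths the shares were 25.7% and 30.0%. The direction turned when only genome-matching reads outside rRNA and tRNA genes were counted, a setting chosen after the data were seen: the share was then 28.9% in the WT library and 35.9% in the AGO1DCR1 library. In that setting the shares at the other lengths were 24.6% in the WT library and 35.1% in the AGO1DCR1 library.

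Transposons and subtelomeric repeats were asked about next, as known sources of double-stranded RNA. Ty elements, the LTR retrotransposons of this yeast, gave 22591 RPM of 22- and 23-nt reads, relative to all inserts of 18 to 30 nt, in the AGO1DCR1 library (Poisson interval 22509.8 to 22673) and 139 in the WT library (132 to 146), 162-fold more. Helicase genes of the Y′ elements, repeats next to telomeres, showed the widest gap, with 9712 against 1.93 RPM, a 5035-fold ratio (3318 to 8391). This class holds the genes named YRF1 only. Other subtelomeric frames with shared reads, such as YIL177C, were counted as protein-coding. LTRs outside full elements were 347-fold higher, the strand opposite to ribosomal RNA 656-fold higher, and the nontranscribed spacers of the ribosomal DNA 209-fold higher. Protein-coding sense reads were 53.4-fold higher. Relative to the median of ratios over genes, the folds were 1.01 for protein-coding sense reads, 3.08 for Ty elements, 95.5 for Y′ helicase genes, 6.57 for LTRs, 12.4 for the strand opposite to ribosomal RNA and 3.96 for the spacers. Ty1 was 188-fold, Ty2 147-fold and Ty3 199-fold higher. Ty4 differed, at 14.4 RPM in the WT library and 9.94 in the AGO1DCR1 library, a direction that flips to 3.27-fold higher in the AGO1DCR1 library when libraries are scaled on rRNA and tRNA reads. Scaled on genome-matching reads the Ty4 ratio was 0.985, and relative to the median of ratios Ty4 was 76.6-fold lower. Ty1 reads of the AGO1DCR1 library were 49.9% antisense, against 5.11% of the WT Ty1 reads. Ty4 reads of the WT library were 95.8% antisense, 146 reads against 6.38 sense reads. In the AGO1DCR1 library 67.0 Ty4 reads were antisense and 62.3 sense, so the lower Ty4 value rested on antisense reads. The Ty ratio was 25.9 with reads of a single genome position. It was 3.38 when each distinct sequence counted once, relative to all distinct sequences of the library. These numbered 1450707 in the WT library and 6736041 in the AGO1DCR1 library, with or without a genome match. The 3.38 is therefore not the ratio of the numbers of distinct Ty sequences.

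Transfer RNAs, small nucleolar RNAs and mitochondrial transcripts, none of them a usual source of double-stranded RNA, were compared in the same way. Transfer RNA reads were 19.5-fold lower, mitochondrial reads 19.9-fold lower and small nucleolar RNA reads 5.39-fold lower. Ribosomal RNA was 3.43-fold lower, 2.40-fold lower when scaled on genome-matching reads and 181-fold lower relative to the median of ratios, but 1.38-fold higher when scaled on rRNA and tRNA reads. Relative to all inserts its direction rested on the 18S fragment, which gave 77.1% of the WT reads of this class: without it, a setting chosen after the data were seen, ribosomal RNA was 1.27-fold higher in the AGO1DCR1 library. The tRNA, mitochondrial and snoRNA classes stayed lower when scaled on rRNA and tRNA reads, by 4.11-fold, 4.20-fold and 1.14-fold. For tRNA and ribosomal RNA this scaling is no independent check, since their own reads are part of its total. Spliceosomal snRNAs were 3.22-fold higher as a class, although 0.0611-fold relative to the median gene, and LSR1 gave 2200 of their 2260 sense AGO1DCR1 reads. The median of the 5 snRNA genes with enough reads was 1.08, and SNR6 and SNR14, named after their values were seen, were 15.4-fold and 11.99-fold lower.

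**Figure D2:**
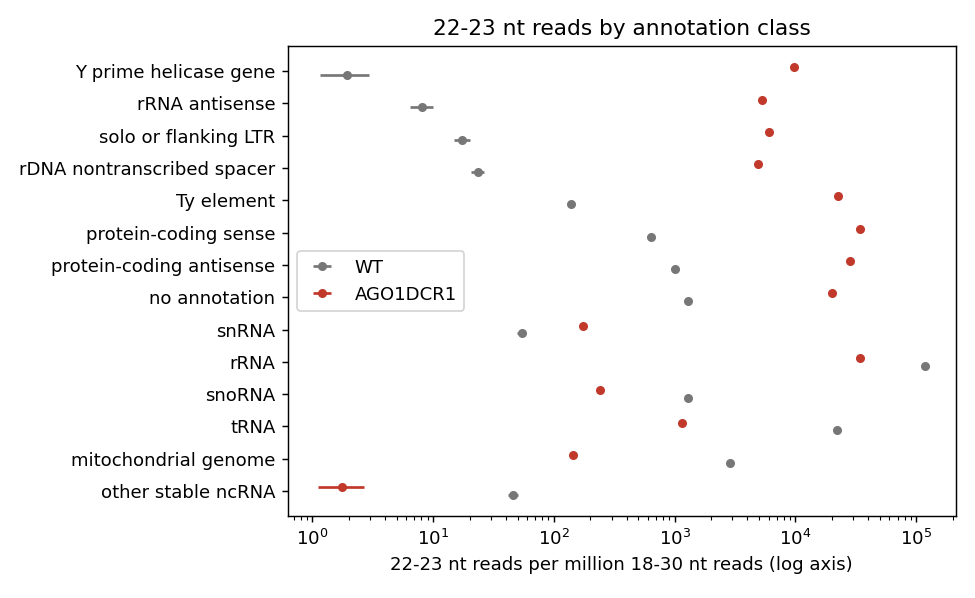
RPM of 22- and 23-nt reads, relative to all inserts of 18 to 30 nt (x axis, log scale) for each annotation class (y axis), with grey points for WT and red points for AGO1DCR1, 1 library each; bars are exact 95% Poisson intervals and are often smaller than the points. Y′ helicase genes lie at 1.93 in the WT library and 9712 in the AGO1DCR1 library, and tRNA lies at 22245 and 1140.

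Cleavage of double-stranded RNA gives reads of both strands. Within protein-coding genes, 45.4% of the AGO1DCR1 reads of 22 and 23 nt were antisense (45.29 to 45.50%), against 60.9% in the WT library (60.12 to 61.58%). The WT share came mainly from YLR162W, a gene of unknown function beside the ribosomal DNA: it held 9448 antisense WT reads, of which 3 were left without reads matching rRNA or tRNA genes. With reads of a single genome position the direction turned, to 13.4% in the WT library (12.60 to 14.18%) and 45.7% in the AGO1DCR1 library. It also turned when distinct sequences were counted, and when reads matching rRNA or tRNA genes were left out, a setting chosen after the data were seen (13.1% and 45.3%). Antisense reads of 25 to 30 nt made up 27.9% in the AGO1DCR1 library and 13.1% in the WT library, without rRNA and tRNA reads and without genes that overlap another gene.

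RNase III enzymes such as Dicer leave 3′ overhangs of 2 nt. In the AGO1DCR1 library, 11085 pairs of equal-length reads on opposite strands had this overhang, the most of all overhangs from -10 to 10 nt and 1.39 times the median of the others, 7958.5. The next most frequent overhang had 8828 pairs. In the WT library 7 pairs had a 2-nt overhang, and the median of the others was also 7. Only reads with a single genome position entered, so most copies of Ty and Y′ elements did not. With all genome matches the AGO1DCR1 ratio was 1.11.

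**Figure D3:**
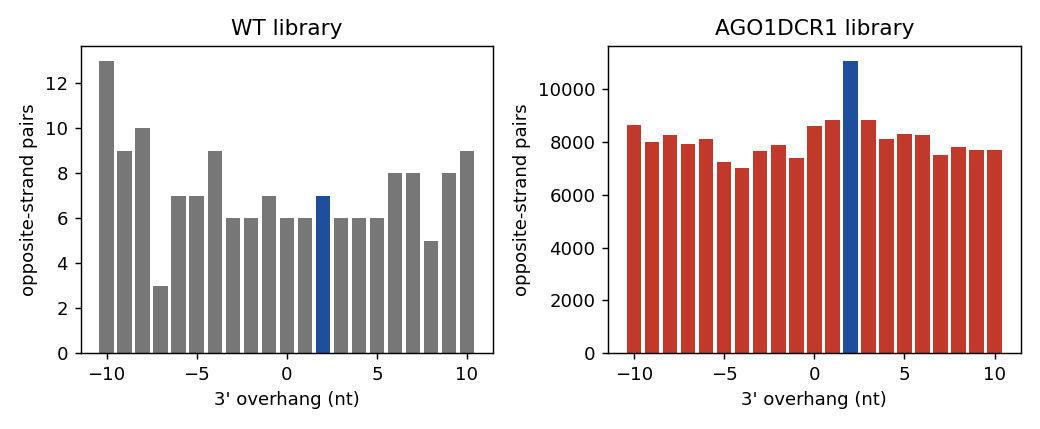
Number of pairs of opposite-strand reads of 22 or 23 nt (y axis) at each 3′ overhang in nt (x axis), in the WT library on the left and the AGO1DCR1 library on the right, with the 2-nt overhang in blue; the y axes differ. The AGO1DCR1 library has 11085 pairs at 2 nt and at most 8828 at any other overhang, and the WT library has 7 at 2 nt.

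Among single genes, the contrast ran mostly one way. Of 1750 genes with at least 50 reads of 22 and 23 nt over both libraries, 1618 were at least 8-fold higher in the AGO1DCR1 library and 43 at least 8-fold lower. The first set held 1515 protein-coding genes, 83 Ty genes and all 6 annotated antisense RNAs with enough reads. The second held 23 snoRNA genes and 16 protein-coding genes, of which 10 were mitochondrial and 6 kept under 1% of their WT reads without reads of rRNA and tRNA genes. The median ratio of the 1750 genes was 52.7, so genes with a smaller ratio lie below the median gene, and the median log2 ratio of the 3514 genes with at least 10 reads was 1.91. Relative to the median of ratios, 221 genes were at least 8-fold higher and 119 at least 8-fold lower. The minimum counts both libraries together, so a gene can pass through its AGO1DCR1 reads alone. Without a minimum, 2265 of 4431 genes were at least 8-fold higher and 73 at least 8-fold lower, at a median ratio of 8.39.

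The 12 genes with the largest ratios were PMA2 and 11 subtelomeric open reading frames, namely YEL076C, YPR203W, YFL065C, YHL049C, YLR462W, YBL111C, YEL075C, YHR218W, YEL076C-A, YIL177C and YJL225C. Near-identical copies share these reads, which were split equally, so the value of any one copy is uncertain. YIL177C on chromosome IX and YJL225C on chromosome X had 17465 and 17459 AGO1DCR1 reads against 2.10 WT reads each, ratios of 6745 (1961 to 58519.6) and 6743. For 10 of the 12 the WT value was under 1 read. With values under 1 read raised to the floor of 3 reads, only 2 of the 12 stay in this set. That setting was chosen after the data were seen. PMA2, a plasma membrane proton pump gene on chromosome XVI, had 6361 AGO1DCR1 reads and under 1 WT read, with a ratio interval from 1399 upwards, and 88.8% of its reads were antisense.

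Genes with reads of mostly a single genome position were picked after their values were seen, as those with large ratios among genes with at least 90% such reads. Genes without a WT read have only a lower bound, as TRP1 with 4071 reads and at least 1101-fold, so the order among these genes is not settled. RDS1, a zinc cluster transcription factor gene, had 4930 AGO1DCR1 reads against 1 WT read, a ratio of 4001 (718 to 158051). SWE1, the kinase that restrains mitosis, had 4926 against 1. TAF2, a TFIID subunit, had 3752 against 1. FAR1, which arrests the cell cycle in response to pheromone, had 4873 against 2, a ratio of 1977 (547 to 16331). PRY3, a cell wall protein gene, had 7232 against 3, a ratio of 1956 (669 to 9488), with 51.6% antisense reads. SWE1, FAR1 and PRY3 lie on chromosome X.

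The 6 smallest ratios were those of 2 snoRNAs, the RNA of the signal recognition particle and 3 open reading frames. SNR34 had 555 WT reads and 3 AGO1DCR1 reads, 228-fold lower (77.6 to 1109). SNR54 had 49 and 1, a 60.4-fold difference (10.3 to 2433). SCR1, the signal recognition particle RNA, had 385 and 6, a 79.1-fold difference (35.998 to 217). YOR072W-B and YJL007C were 92.2-fold and 79.99-fold lower, but almost no WT read was left in either without reads of rRNA and tRNA genes. The Ty frame YJL114W had 109 WT reads, all antisense, and 2.67 AGO1DCR1 reads. Antisense reads in the AGO1DCR1 library were most numerous in TAR1, which lies antisense to ribosomal RNA (13959.5, against 2740 in the WT library), followed by YIL177C, YJL225C, YRF1-1, YRF1-5 and YRF1-8.

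Gene lists fixed before the data were examined were placed among 10000 random lists of matched level, on reads of both strands and on antisense reads alone, and these placings often differed. All 8 subtelomeric Y′ helicase genes (YRF1) were at least 8-fold higher, with a median log2 ratio of 9.94 at percentile 100, and 99.98 on antisense reads. YRF1-1 and YRF1-5 each had 17421 AGO1DCR1 reads and 2.27 WT reads, and none of these AGO1DCR1 reads matched a single position. Copies share reads, which were split equally, so the 8 members are not independent. Their percentiles therefore do not rest on 8 separate values. The 6 flocculin genes, which encode cell adhesion proteins, had a median of 6.93, at percentile 96.8 but 29.3 on antisense reads, led by FLO5 with 7376 reads against 1.38 and FLO9 with 4685 against 1.17. The 9 tandem-repeat genes of copper, salt and asparagine metabolism had a median of 8.03, at percentile 86.6 but 18.1 on antisense reads. Its sodium pump genes ENA1 and ENA2 had 6898 and 6755 reads, split between copies, against 1.67 each. Of 89 Ty genes, 88 had enough reads and 84 lay above 0, with a median of 6.93. Their percentile was 10.7 for both strands and 100 for antisense reads. YHR214C-B and YJR029W had the most reads, at 187-fold and 170-fold. Only 0.0918% and 0% of their AGO1DCR1 reads matched a single position, so Ty genes also share reads and are not independent members.

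Hexose transporter genes had a median log2 ratio of 3.36 (percentile 96.0), with all 14 measured members above 0. HXT5 was 71.8-fold higher and HXT2, with no WT read, at least 69.2-fold higher. The 5 measured galactose genes had a median of 5.91 (percentile 67.3). GAL1 had no WT read and was at least 524-fold higher, and GAL4, which activates the galactose genes, was 378-fold higher (104 to 3127). Of 24 seripauperins, small cell wall proteins, 4 were measured, with a median of 1.72 (percentile 96.3). None of the 4 had a WT read, so they could only lie above 0. PAU2 and PAU7 were at least 15.7-fold and 13.3-fold higher. The 8 measured RNA decay and antiviral genes had a median of 1.82 (percentile 94.4), with SKI3 90.6-fold and SKI2 at least 44.1-fold higher. The median WT level was also 0 RPM in the RNA decay and galactose lists, and 0.0158 RPM in the hexose transporter list. Members without a WT read could only lie above 0 in these lists too. The seripauperin and RNA decay medians lie below the 1.91 of all measured genes, so their percentiles hold only against lists of matched level. On antisense reads the hexose transporter, galactose, seripauperin and RNA decay lists lay at percentiles 80.8, 77.0, 60.7 and 84.0.

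Genes regulated by noncoding transcription, meiosis, mating or chromatin were also listed. The 8 measured genes with known antisense or upstream noncoding transcripts had a median of 3.36 (percentile 71.2), and the phosphate-responsive genes PHO5 and PHO84 were 863-fold and 132-fold higher. Meiosis genes had 2.64 (76.1), at a median WT level of 0 RPM, with IME2 at least 44.6-fold and HOP1 at least 28.7-fold higher. Core histone genes had 2.30 (49.6), with HTZ1 at least 30.8-fold and HHT2 46.3-fold higher (7.97 to 1859). Mating genes had 1.63 (49.2), with MF(ALPHA)2 144-fold (25.6 to 5737) and STE6 at least 40.3-fold higher. Marker genes had 2.37 (47.6), where TRP1 had 4071 AGO1DCR1 reads and no WT read and CAN1 was 63.3-fold higher. The COS family had 2.91 (12.4), with COS6 37.3-fold and COS5 27.3-fold higher. On antisense reads the percentiles of these lists, in the order given, were 74.0, 10.5, 65.2, 19.2, 20.955 and 15.4.

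Highly expressed genes for growth, such as those for translation and glycolysis, had low percentiles on reads of both strands but not on antisense reads. Cytosolic ribosomal protein genes had a median log2 ratio of 0.29, at percentile 0, with 53 of 88 measured members above 0. The member with most reads, RPP1, matched the list by its name pattern and encodes a subunit of RNase P, and RPP2B was 5.03-fold higher. Translation factor genes had a median of 0.19 (percentile 0.01). SUP45 was 22.3-fold higher and EFB1 2.21-fold lower, or 2.15-fold higher with scaling on rRNA and tRNA reads. Scaled on genome-matching reads EFB1 was 1.54-fold lower, and relative to the median of ratios 117-fold lower. Chaperone genes had 0.69 (percentile 0.21), with SSA1 14.98-fold and SSA2 7.64-fold higher. Glycolysis and fermentation genes had 2.60 (percentile 0.57), with ADH1 113-fold and PDC1 16.02-fold higher. On antisense reads the ribosomal protein list lay at percentile 97.3, translation factors at 42.7, chaperones at 33.9 and glycolysis at 60.5. The medians of the first 3 of these lists turn negative relative to the median gene. The snoRNA list had -1.81 and the list of snRNAs and other stable RNAs -1.41, both at percentile 0, and at 5.49 and 68.6 on antisense reads. SNR3 and SNR9 went the other way, 16.2-fold and 9.33-fold higher, as did LSR1, the U2 snRNA, at 30.9-fold (23.8 to 40.8), while TLC1, the telomerase RNA, had a ratio of 1.13 (0.708 to 1.83).

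Convergent neighbouring genes, whose transcripts can pair at their 3′ ends, were compared with tandem and divergent neighbours. In the AGO1DCR1 library the 1451 convergent regions held 85.5 reads per kb, the 2644 tandem regions 78.0 and the 1421 divergent regions 112. The median region gave another order, 27.7 reads per kb for convergent, 6.92 for tandem and 6.10 for divergent pairs. Without the 10 regions with the most reads of each orientation, chosen after the data were seen, the convergent density was 1.27 times the tandem and 1.99 times the divergent density. In the WT library the densities were 6.13, 3.96 and 1.57, while the median regions held 0.0287, 0.707 and 0 reads per kb, which puts tandem above convergent regions.

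Outside nuclear rRNA and tRNA genes, reads of 22 and 23 nt formed 1154 clusters with at least 100 reads, some of them over mitochondrial rRNA and tRNA genes, and 1085 of them had a higher RPM in the AGO1DCR1 library. The cluster with the most AGO1DCR1 reads lay on chromosome XII at 467559 to 472468 (R64), over ribosomal spacers and the asparaginase gene ASP3-1. It held 49038 AGO1DCR1 reads and 32 WT reads. The next 4 also lay on chromosome XII, at 458422 to 460720, 472573 to 482048, 482153 to 485700 and 485805 to 489352, among ribosomal spacers, 5S genes and the other ASP3 copies. The sixth, on chromosome IX at 272 to 7335, covered YIL177C at the left telomere with 18982 reads against 8.07.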

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

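Pairs among reads without a genome match were looked for only after the data were seen. Reads of 22 and 23 nt with no genome match within 1 mismatch take no part in the comparisons by genome position, and they held more pairs than in the WT library. Among AGO1DCR1 sequences read at least 10 times, 199 opposite-strand pairs had a 2-nt 3′ overhang, against at most 141 at any other overhang from -4 to 4 nt, and the WT library had 0 such pairs. That library had at most 6 pairs at any overhang, from 1900 sequences against 5799, so it was too thin to show or lack a preference for 2 nt. Such unmatched reads were 41.3% of the AGO1DCR1 reads of these lengths and 13.9% of the WT reads. The AGO1DCR1 sequences searched for pairs held only 120735 of 2286362 such reads, and the WT sequences 119306 of 286267. The pairs therefore describe a small part of the unmatched AGO1DCR1 reads.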

How the results depend on the processing

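The settings with genome-matching reads, up to 1 mismatch, 22 nt alone, all genome matches for pairs, without the most frequent WT sequence, without the regions with most reads and without Ty or LTR, all settings for ribosomal RNA, for other classes and without mitochondrial rRNA and tRNA reads, the Ty fold relative to the median of ratios, and the removal of rRNA and tRNA reads from the antisense share, were chosen after the data were seen. The floor for values under 1 read and the removal of rRNA and tRNA reads from the gene and cluster counts were also chosen then. No paired analysis was possible because there was 1 library per strain, and leaving out a library leaves no comparison.

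The ratio of shares of 22 and 23 nt, 2.18, was 1.51 for 23 nt alone, 2.55 for 21 to 23 nt, 4.13 without rRNA and tRNA reads, 3.25 for distinct sequences, 1.62 for genome-matching reads, 3.42 for these without rRNA and tRNA reads and 2.52 for 19 to 23 nt among the latter. Without mitochondrial rRNA and tRNA reads too, it was 4.14, and 2.89 for genome-matching reads. The 5′ U difference, AGO1DCR1 minus WT, was -35.3 points. It was -46.6 for 23 nt alone, -22.97 without rRNA and tRNA reads, -8.72 for distinct sequences, -36.2 for genome-matching reads and -8.03 without the most frequent WT sequence, and turned to 6.96 for genome-matching reads without rRNA and tRNA reads. Without mitochondrial rRNA and tRNA reads too, these were -23.9 and 10.4. The antisense difference, -15.5 points, turned to 32.3 with single-match reads, 32.1 for distinct sequences, 32.3 without rRNA and tRNA reads, with or without mitochondrial ones, and 32.4 also without overlapping genes. In YLR162W, 3 of the 9448 WT reads were left without rRNA and tRNA reads; other causes were not tested.

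The Ty fold of 162 was 25.9 with single-match reads, 770 scaled on rRNA and tRNA reads and 232 scaled on genome-matching reads. It was 3.08 relative to the median of ratios and 173 with up to 1 mismatch. For distinct sequences, relative to all distinct sequences of the library, it was 3.38. The ribosomal RNA ratio of 0.292 turned to 1.27 without the most frequent WT sequence and to 1.38 scaled on rRNA and tRNA reads, while it was 0.417 scaled on genome-matching reads and 0.00553 relative to the median of ratios. Relative to the median of ratios, the protein-coding antisense fold of 28.5 turned to 0.541 and the snRNA fold of 3.22 to 0.0611. The overhang ratio of 1.39 was 1.47 for 23 nt, 1.48 weighted by the smaller read number, 1.32 for 22 nt and 1.11 with all genome matches. The 1618 higher genes became 2265 without a minimum, where more genes were counted, and 737 with a minimum of 200 reads, where fewer were. Relative to the median of ratios they became 221. The 43 lower genes became 73 without a minimum, 9 scaled on rRNA and tRNA reads, 119 relative to the median of ratios and 66 at 4-fold. The convergent over tandem ratio of 1.10 was 1.14 without overlaps, 1.27 without the 10 regions with most reads and 1.22 without Ty or LTR. Over divergent regions, 0.766 became 1.99 without those 10 regions and 0.778 without Ty or LTR. The 1154 clusters became 2123 with a minimum of 30 reads and 626 with 300. Relative to the median of ratios the list medians turned to -0.61 for translation factors, -0.055 for chaperones and -0.40 for ribosomal proteins. With pseudocounts of 0.1 and 5, 18 of 20 lists stayed above 0. For the other shifts the cause was not tested. Depth limits the values of single genes in the WT library, where 3 reads equal 0.284 RPM.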

Other observations

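The tests of library scaling, of other read lengths, of sense-strand share and of reads shared by the PMA genes were chosen after their results were seen. The other 3 were chosen before, although the Ty and Y′ pairs were first counted over all element copies and only then per distinct pair.

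Some loci of the AGO1DCR1 library gave reads of nearly 1 strand. Of 1084 clusters with at least 100 AGO1DCR1 reads of 22 and 23 nt, 24 had at least 90% of them on one strand. Of these, 11 had a higher RPM in the WT library, over snoRNA genes, mitochondrial sequence and YLR162W, and 5 were mitochondrial. The examples here had more reads in the AGO1DCR1 library and were chosen after their values were seen. The cluster with the most AGO1DCR1 reads lay on chromosome V at 248512 to 250271 (R64), where no gene is annotated, beyond CAJ1. It held 10408.5 AGO1DCR1 reads against 4.37 WT reads, 4.49% of them on the plus strand, and 96.3% matched a single position. LSR1, the U2 snRNA on chromosome II, had 2200 sense and 9 antisense reads. On chromosome XIII at 481236 to 481744, between YMR106W-A and SPG4, 889 reads lay in a cluster without a WT read, 2.59% of them on the plus strand.

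The excess of Ty and Y′ reads of 22 and 23 nt in the AGO1DCR1 library could come from scaling, but a single factor per library acts on all lengths alike, and the Ty fold at 22 and 23 nt was 56.3 times that at 25 to 30 nt (51.0 to 62.1). The size of the excess does depend on scaling: relative to the median gene Ty reads were 3.08-fold and Y′ reads 95.5-fold higher. More Ty RNA or more breakdown at every length is argued against as the whole source, because the Ty fold at 25 to 30 nt was 1.78% of that at 22 and 23 nt, and the Y′ value was 0.920%. Reads of 25 to 30 nt were nonetheless 2.88-fold higher for Ty elements and 46.3-fold higher for Y′ helicase genes. At that length the ratio was 0.303 for protein-coding sense reads and 0.0637 for antisense reads, so a part of the excess was not confined to 22 and 23 nt. Dicer cleavage stays open in these elements. Set in advance, a number at 2 nt not above the most frequent other overhang was to count against it. Distinct pairs at a 2-nt overhang met this, at 0.974 times the most frequent other overhang. The interval (0.945 to 1.004) also holds values above it, so this result does not decide. That other overhang was -10 nt, at the edge of the range, with 8470 distinct pairs against 8247 at 2 nt. Every remaining overhang had fewer than 2 nt, at most 8157, and the median of the others was 7923.5. Counted over all copies the ratio to the most frequent other overhang was 1.04, and weighted by read number 1.14, so the order depends on the counting. Across the whole genome, for reads with a single position, the 2-nt overhang was 1.26 times the most frequent other.

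Reads of 19 to 21 nt beside those of 22 and 23 nt in the AGO1DCR1 library may be 23-nt reads that lost nucleotides at the 3′ end. Of these reads 53.8% shared a 5′ end with a 23-nt read and 46.5% a 3′ end, a difference of 7.25 points. This lies between the 5 points and the 10 points set in advance, so it does not decide. In the WT library the difference was -2.69 points. Pooled over all protein-coding genes, 52.7% of the 19- to 21-nt reads were sense, where at least 70% was needed. This was close to the 54.7% at 22 and 23 nt. Breakdown of abundant RNA is thus argued against as the main source of the pooled reads only. Genes with abundant RNA were not tested apart at 19 to 21 nt, so breakdown stays open for them. At 22 and 23 nt, 28.2% of AGO1DCR1 reads were antisense in the glycolysis list and 28.9% in the translation factor list. The shares were 34.9% for ribosomal proteins and 40.3% for chaperones, against 45.4% in all protein-coding genes. Breakdown also stays open for ribosomal RNA, with 80.2% sense reads, and for snRNAs, with 99.6%. Their reads of 22 and 23 nt were, however, 86.7% and 98.3% sense.

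PMA1 and PMA2, which encode 2 forms of the plasma membrane proton pump and are 80.4% identical, had opposite strands in the AGO1DCR1 library. PMA1 had 4900 sense and 310 antisense reads, and PMA2 713 sense and 5648 antisense reads. Reads shared between the copies are argued against, because 94.2% of the PMA1 sense and PMA2 antisense reads matched a single position. A candidate explanation is a duplex of PMA1 mRNA with antisense RNA of PMA2. Aligned to each other, these reads paired most often at a 2-nt overhang, with 192 pairs against 173 at the next, a ratio of 1.11 (0.904 to 1.36) that the counts are too few to set apart from 1. The median of the other overhangs was 151. Sense and antisense reads within PMA1 gave 40 pairs at 2 nt, against at most 39 elsewhere and a median of 30.5. Within PMA2 they gave 65, against at most 67 and a median of 48.5. A raised number at 2 nt was thus not particular to pairs between the 2 genes.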
